A study of Mus musculus with 10 samples.

How the data were processed

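Total RNA from hearts of 10 mice was sequenced, 5 wild-type (WT) and 5 knockout for Lmna on both alleles (Lmna KO), all on a C57BL/6 background and 14 days old. Lmna encodes the nuclear lamina proteins lamin A and lamin C. Per the labels, RNA was isolated with a miRNeasy kit, libraries were made with a TruSeq kit and each library was run on 3 lanes. The labels give each library its own animal number, and the design text counts 5 mice in each genotype, so the libraries were treated as separate animals. Groups were taken from the genotype label.

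Per the submitters' processing notes, TopHat2, Cufflinks and edgeR were used with the genome build mm10. Their versions, roles and settings, the read counter, the use of strand and the filter on low genes are not given in the sources used here. The authors deposited a table of 14647 rows with 1 signal value per gene and library, which by the name of the deposited sheet is a CPM value of the effective library size, that is, of the library total multiplied by a scaling factor. The authors also deposited a table of their own comparison, with a signal level per genotype, a log2 ratio, a p-value and a false discovery rate (FDR) for 14646 rows, and gene positions in mm10. Which edgeR test gave these p-values is not stated.

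Within each library all values were whole multiples of the value of 1 read. Whole reads came back for 100% of values in every library, within a tolerance of 0.01 read. The recovered totals were 15259545 to 22146030 reads per library, and 1 read was worth between 0.0447 and 0.0672 signal units. Recovered reads were used for the count-based alternatives. A total of 21 rows whose gene name had been turned into a date, 1 of them repeated, could not be assigned to a gene. They held 0.1336% to 0.2037% of the reads of a library and were left out, which left 14626 genes. No other per-library column was present in the tables.

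The main test was limma on log2(signal + 0.5) with genotype as the only factor, empirical Bayes moderation with an intensity trend, and a two-sided Benjamini-Hochberg adjusted p under 0.05. It covered the 12855 genes with a mean signal of at least 1 over all 10 libraries. Fold changes are on the log2(signal + 0.5) scale, which understates the change of low genes. Where a fold is given, it is the ratio of the mean signals. The targeted gene was also tested with an exact permutation test of 5 against 5 values. Gene lists were tested with camera, a competitive test of a list against the other genes, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over all lists. Of 48 lists written from textbook knowledge, 45 had at least 5 measured members. The lists of mitochondrially encoded mRNAs, of lymphocyte markers and of lung and thymus epithelium markers had fewer and were not tested. Camera was repeated with the correlation estimated from the data.

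Genes were named by a rule. It took Lmna, up to 12 rises and 12 falls with a mean signal of at least 5, an adjusted p under 0.05 and no overlap between the genotypes, up to 4 called members of each list (or the most abundant member where none was called) and 18 genes fixed by name. Unnamed gene models and sex-linked markers were left out of the rises and falls. The rule gave 69 genes. The main test, the lists, the naming rule and the alternatives were fixed before the data were examined. After the 5th knockout library was seen to stand apart, the rule for rises, falls and list members was applied to the fit without it, which gave 72 further genes, of which 32 are named. Some genes that the rule took are not reported here. A list of genes under feedback control by ERK signalling and 10 further genes (Lrat, Rbm46, Ankrd35, Myl4, Sln, Sbk2, Bmp10, Cacna1s, Dusp5 and Spry1) were chosen after their values were seen. Other members of the ERK list, and Dhrs9 of the atrial list, are given beside them.

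Alternatives were pseudocounts of 0.1 and 1, no filter, a minimum mean signal of 5, median-of-ratios and upper-quartile scaling, leaving out each library in turn, the replicate number as a block, a sex-linked covariate, robust moderation, library weights, edgeR's quasi-likelihood test, DESeq2, stricter thresholds and, for lists, an estimated correlation and fry. Alternatives chosen after the data were seen were edgeR's exact test, that test without the 5th knockout library, leaving out the 2nd and 5th knockout libraries together, and the estimated correlation without the 5th knockout library. Each group held 3 libraries with and 2 without Y-linked transcripts. Pairs of libraries of a genotype differed by more than sampling noise, with a chi-square per degree of freedom of at least 4.9, so no library was counted as a repeat of another.

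The functions were tested on simulated reads with the spread of the WT libraries. In the simulated comparison of 5 Lmna KO with 5 WT libraries over 12855 genes, 85.1% of genes changed 1.5-fold, 97% of those changed 2-fold and 100% of those changed 4-fold were recovered, with 12 calls among unchanged genes. The knockout libraries varied more than the WT libraries, so these shares apply to a smaller spread than that of the real comparison. R 4.3.3, limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0 were used. Genes that share sequence with a paralog or a processed pseudogene, such as Myh6 and Myh7 or Rplp0, carry an uncertainty that the unstated counting leaves open.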

Results

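RNA profiles were compared between hearts of 5 WT and 5 Lmna KO mice at 14 days of age, to find which transcripts differ in the heart between the genotypes. Values are signal units, CPM values scaled to the effective library size. Library totals were 15259545 to 22146030 reads. Transcript positions are those of the deposited table in the mouse build mm10.

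Lmna, the targeted gene (chromosome 3, 88481148 to 88503352), fell in the knockout hearts. Its signal was 106 ± 2.95 (SD, n = 5) in WT and 33.7 ± 10.3 (SD, n = 5) in Lmna KO, 0.318 of the WT mean. Every knockout library, between 22.1 and 48.9, lay below every WT library, between 102.3 and 110.1, so the labels and the targeted gene matched in all 10 libraries. The log2 change was -1.69 with a standard error of 0.17 (limma adjusted p = 0.00461). The two-sided exact permutation p was 0.00794, the smallest that 5 against 5 values allow. The values are for the whole gene, and which exons the remaining reads came from was not analysed here.

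A total of 26 genes changed between the genotypes by the limma test, 15 higher and 11 lower in Lmna KO. Among the rises were Nmrk2, a nicotinamide riboside kinase of NAD synthesis (3.98 ± 1.62 in WT and 18.8 ± 7.52 in KO, SD, n = 5 each, log2 change 2.07), and Nr4a1, an immediate-early nuclear receptor (17.7 ± 4.74 to 68.6 ± 29.2, log2 change 1.85). Psat1, an enzyme of serine synthesis, rose from 4.49 ± 0.191 to 14.4 ± 4.22. Etv5, a transcription factor induced by ERK signalling, rose from 21.6 ± 1.24 to 50.0 ± 13.5. The exchanger gene Slc24a2 rose by 1.81 on the log2 scale, Rasgef1b by 1.22, the endothelial diaphragm gene Plvap by 1.15, Ndnf by 0.86 and Fam189a2 by 0.48. The imprinted neighbours H19 and Igf2, both expressed strongly in fetal tissue, rose by 0.96 and 0.78.

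Besides Lmna, the falls included Rpl3l, the muscle form of a ribosomal protein (49.2 ± 8.02 to 20.3 ± 5.58, SD, n = 5 each, log2 change -1.29). Pdp2, a phosphatase that activates pyruvate dehydrogenase, fell from 28.9 ± 4.19 to 14.5 ± 1.04. Hk2, which phosphorylates glucose, fell from 334 ± 27.8 to 185 ± 37.2, and Pcca, a subunit of mitochondrial propionyl-CoA carboxylase, from 47.6 ± 4.15 to 28.3 ± 3.89. Efcab2 fell by 0.93 on the log2 scale and Txn2, the mitochondrial thioredoxin, by 0.78. Adjusted p-values of the genes named here other than Lmna ran from 0.00644 for Rasgef1b to 0.0497 for Ndnf (limma). The WT and KO values of all 26 genes did not overlap. Among all tested genes this was so for 10.3%, where chance gives 0.794%. In all, 2679 genes had an unadjusted p under 0.05, against 643 expected by chance.

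**Figure D1:**
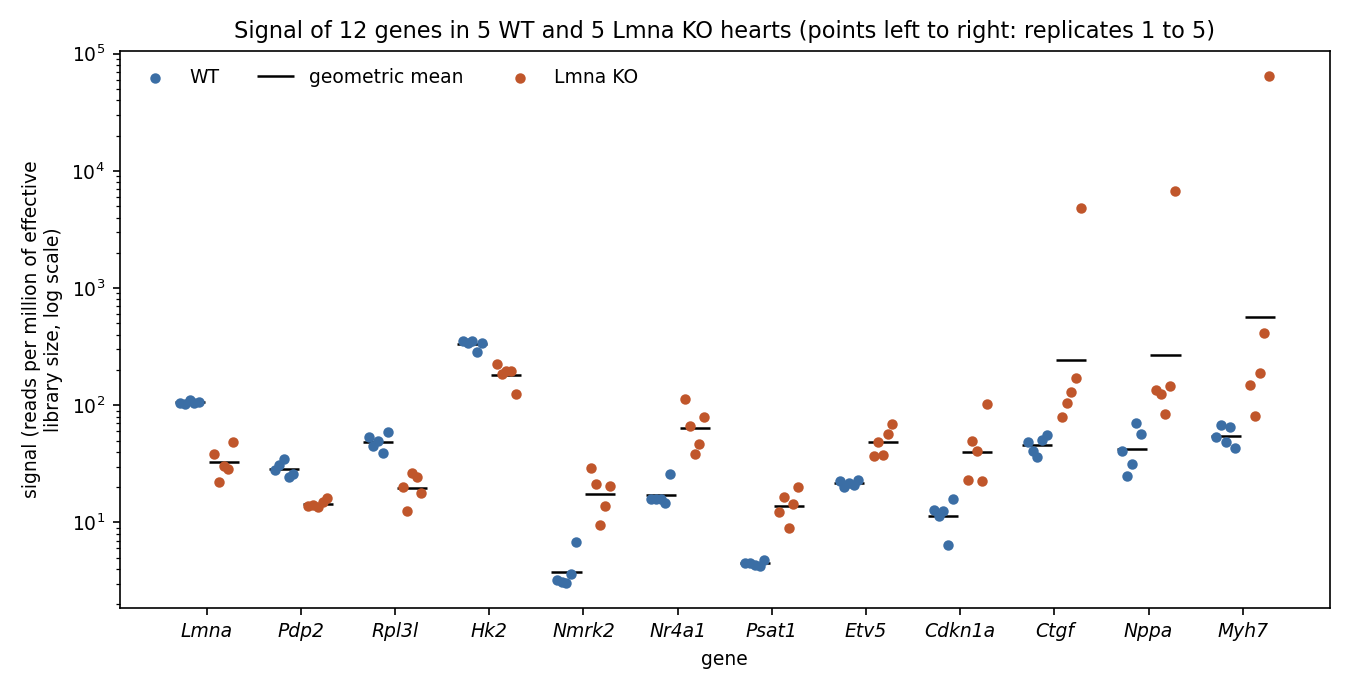
Signal per library (log axis) of 12 genes in WT (blue) and Lmna KO (orange) hearts, with black bars at the geometric means of 5 libraries. Lmna lies between 22.1 and 48.9 in every knockout library, and the 5th knockout library reaches 64424 for Myh7, 6767 for Nppa and 4791 for Ctgf.

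The number of called genes changed with each library left out. The 5th knockout library had a mean correlation of 0.905 with the WT libraries, against 0.962 to 0.985 for the other knockouts and 0.989 to 0.991 among WT libraries. It set the first principal component, with 56.3% of the variance, and the 2nd knockout library set the second, with 18.4%. Without the 5th knockout library 640 genes were called by limma, 292 higher and 348 lower in Lmna KO, and all 26 genes were among them. The balance of directions differed between tests that also covered different genes. Without the same library edgeR's exact test, chosen after the data were seen, called 601 higher and 450 lower. It covered 14626 genes with no minimum signal, against 12855 for limma. Whether the test or the genes set the difference was not tested. Without WT libraries 1 to 5 in turn the limma counts were 6, 7, 6, 9 and 9. Without knockout libraries 1 to 4 they were 19, 14, 11 and 39. Of the called genes named above, Lmna, Pdp2, Psat1, Slc24a2 and Rasgef1b kept their call in all of 24 alternatives. The call was lost in 4 of these for Plvap, 5 for Nmrk2 and Nr4a1, 6 for Etv5 and Rpl3l, 7 for H19, 8 for Efcab2, 9 for Pcca, 11 for Txn2 and Fam189a2, 13 for Igf2, 14 for Hk2 and 16 for Ndnf. Leaving out the 1st WT library ended the call of each of these 13 genes (limma adjusted p from 0.0763 for Plvap to 0.16 for Igf2), and so did leaving out the 3rd (0.0872 for Plvap to 0.185 for Ndnf). Their log2 changes moved little. Without the 1st WT library they were, for instance, 1.17 for Etv5, -0.857 for Hk2 and 0.895 for H19, against 1.154, -0.877 and 0.961 with all libraries. The lost calls thus do not mean that these WT libraries set the changes. Leaving out the 5th knockout ended none.

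**Figure D2:**
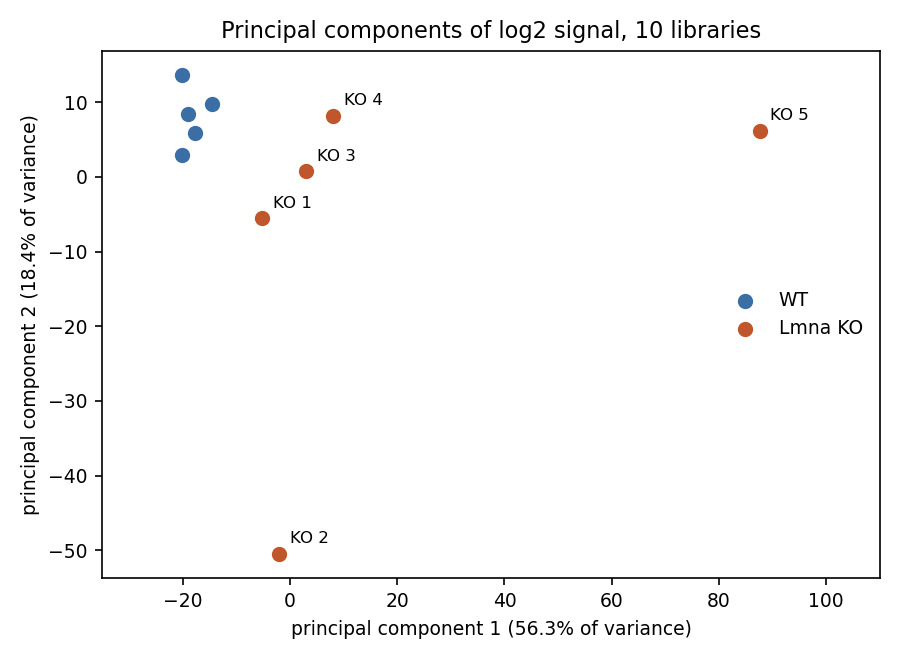
First and second principal component of log2 signal for 10 libraries, WT in blue and Lmna KO in orange, the knockouts with their replicate numbers. The 5th knockout library stands apart on the first component (56.3% of the variance) and the 2nd on the second (18.4%).

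In the fit without the 5th knockout library, with 5 WT and 4 knockout hearts, 8 of 28 members of the fetal and stress list rose and 20 did not pass (camera adjusted p = 0.00965, adjusted p = 0.327 with an estimated correlation). Myl7 and Nppa, which the atrial marker list also holds, were among the 8. Nppb and Acta1 were among the latter (limma adjusted p = 0.277 and 0.776). Myh7, the fetal myosin heavy chain, was 55.8 ± 10.7 in WT (SD, n = 5) and 208 ± 144 in these knockouts (SD, n = 4). Its limma adjusted p was 0.0267 there and 0.223 with all libraries. Nppa, the atrial natriuretic peptide gene and also an atrial marker, was 45.1 ± 19 and 122 ± 26.7 (limma adjusted p = 0.016 and 0.177). Ctgf, a matricellular factor, was 46.3 ± 7.96 and 121 ± 38.7 (limma adjusted p = 0.00878 and 0.179). In this fit Ahsg rose by 2.05 on the log2 scale, Tnni1, the fetal troponin I, by 1.46, Atf3 by 1.38 and Ankrd1 by 1.18. Akap5, an anchoring protein of protein kinase A, fell from 19.3 ± 3.24 to 6.62 ± 1.84. Lrtm1, the integrin gene Itgb6, Fam81a and Fhl2 had log2 changes of -1.63, -1.47, -1.35 and -0.70 and fell too. These 9 genes had limma adjusted p-values between 2.83e-04 and 0.0313 in this fit, and between 0.0665 and 0.146 with all libraries.

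Of 45 gene lists, 25 were called by camera with the preset correlation, 14 toward higher and 11 toward lower signal in Lmna KO. With an estimated correlation camera called 0, with a smallest adjusted p of 0.219 and 7 lists at an unadjusted p under 0.05, and fry called 11. Without the 5th knockout library the preset correlation gave 26 calls, 24 of them on the same lists in the same direction, and the estimated correlation gave 0. Counts of members below are over all genes tested, and the count adjusted over the list alone follows. Many members passed in neither, so each list is described by its median log2 change. Leaving out the 5th knockout library moved the median by over 1.5 times for 10 called lists. It then was 0.42 for glucocorticoid and fasting genes, 0.16 for FOXO targets, 0.15 for atrophy genes, 0.11 for autophagy genes and 0.025 for the integrated stress response. It was -0.11 for glycolysis, -0.14 for calcium handling, 0.30 for atrial, 0.305 for epicardial and -0.32 for erythroid markers.

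Of 5 energy metabolism lists 4 were called toward lower signal with the preset correlation and 0 with an estimated one. TCA cycle genes had a median log2 change of -0.39, and 0 of 25 measured members passed over all genes while 12 fell when adjusted over the list alone (camera adjusted p = 5.21e-08, adjusted p = 0.327 with an estimated correlation). The median was -0.22 to -0.37 in knockouts 1 to 4 and -0.85 in the 5th. With the 5th knockout library left out 9 members fell, among them Mdh2 (759 ± 44.8 in WT, SD, n = 5, and 555 ± 95.8 in KO, n = 4, limma adjusted p = 0.0422), Idh3a, Dld and Sdha (0.0251, 0.0187 and 0.0434). Complex I genes had a median of -0.35 over 36 members and genes of complexes II to V one of -0.28 over 40, with 0 members past the threshold in either count (camera adjusted p = 2.35e-07 and 2.74e-07, adjusted p = 0.465 for both with an estimated correlation). The complex I median was -0.10 to -0.13 in knockouts 1, 3 and 4, -0.72 in the 2nd and -0.63 in the 5th. That of cardiomyocyte markers, a list not called, was -0.07 to -0.11, -0.72 and -0.74 in the same libraries. For complexes II to V it was -0.09 to -0.13 in knockouts 1, 3 and 4, -0.55 in the 2nd and -0.51 in the 5th. Ndufs1, of complex I, was 1065 ± 50.4 in WT and 767 ± 198 in KO (SD, n = 5 each, limma adjusted p = 0.176). It fell with the 5th knockout library left out, to 855 ± 26.6 (SD, n = 4, log2 change -0.32, limma adjusted p = 0.0347). Atp5b and Cycs, of the list of complexes II to V, had log2 changes of -0.14 and -0.63 that did not pass (-0.33 for Cycs without the 5th knockout library). Glycolysis genes had a median of -0.27, and 1 of 23 members, Hk2, fell in both counts (camera adjusted p = 0.00708, adjusted p = 0.465 with an estimated correlation). The median was -0.05 to -0.20 in knockouts 1 to 4 and -0.63 in the 5th. Fatty acid oxidation genes were not called (median -0.23 over 37 members, 0 past either count, camera adjusted p = 0.0628), and Fabp3 had a log2 change of -0.32. Their median was -0.095 without the 5th knockout library. With the preset correlation they were called toward lower signal without the 1st WT or the 3rd or 4th knockout library (camera adjusted p = 0.0441, 0.0212 and 0.0149, medians -0.235, -0.255 and -0.29). With an estimated correlation and all libraries the camera adjusted p was 0.613.

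Both lists of cell division genes were called toward lower signal with the preset correlation and neither with an estimated one. The G2/M and mitosis list had a median log2 change of -0.80, and 0 of 31 members passed over all genes while 21 fell when adjusted over the list alone (camera adjusted p = 3.27e-11, adjusted p = 0.327 with an estimated correlation). Its median was -0.26 to -0.94 in knockout libraries 1 to 4 and -1.62 in the 5th, and it ranged from -0.48 to 0.30 among WT libraries, a range that held the 1st knockout (-0.26). Top2a was 20.4 ± 5.44 in WT (SD, n = 5) and 9.87 ± 2.39 in knockouts 1 to 4 (SD, n = 4), and both it and Mki67 fell in that fit (limma adjusted p = 0.0284 and 0.0313). The E2F targets and DNA replication list had a median of -0.17 and 0 of 31 members past either count (camera adjusted p = 0.0135, adjusted p = 0.327 with an estimated correlation). The median was -0.02 in the 1st knockout and -0.065 in the 5th, both within the WT range of -0.08 to 0.11, and -0.17 to -0.24 in the 2nd to 4th. Leaving out the 4th WT or the 4th knockout library ended this call (camera adjusted p = 0.057 and 0.0553, medians -0.145 and -0.17). Pcna and Cenpf had log2 changes of 0.19 and -0.82 that did not pass, and of 0.03 and -0.43 without the 5th knockout library.

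Lists of p53 targets, senescence and TGF-beta signalling were called toward higher signal with the preset correlation. Over all genes 0 members of each passed. Adjusted over the list alone, 6 of 28 p53 targets rose and 0 fell, 8 of 26 senescence genes rose and 2 fell, and 7 of 30 TGF-beta genes rose and 0 fell. Median log2 changes were 0.205, 0.31 and 0.25 (camera adjusted p = 0.00381, 0.00195 and 1.94e-04, adjusted p = 0.219, 0.252 and 0.268 with an estimated correlation). In the 5th knockout library the medians were 0.30, 0.32 and 0.21, and in knockouts 1 to 4 they were 0.09 to 0.21, -0.007 to 0.51 and 0.10 to 0.43. Cdkn1a, the p21 inhibitor of the cell cycle, is a member of the first 2 lists. The FOXO, atrophy, glucocorticoid and circadian lists described below hold it too. The FOXO list also shares Pdk4, Irs2 and other genes with the glucocorticoid list, and further members with the atrophy and autophagy lists. These lists are thus not independent of each other. Cdkn1a was 11.8 ± 3.39 in WT and 47.4 ± 32.5 in KO (SD, n = 5 each), with a limma adjusted p of 0.0747. It lay above every WT library in 5 of 5 knockouts and rose without the 5th (limma adjusted p = 0.0175). Perp, Btg2, Phlda3, Igfbp3 and Tgfb2 rose in the same fit, by 0.85, 0.66, 0.63, 0.97 and 0.53 on the log2 scale (limma adjusted p between 0.0026 and 0.0486). Ccng1 and Vegfa had log2 changes of -0.61 and -0.34 with all libraries and did not pass, and Ccng1 had one of -0.32 without the 5th knockout library. Apoptosis genes were not called (median 0.005 over 29 members, 0 past either count, camera adjusted p = 0.901).

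Glucocorticoid and fasting genes had the highest median among the called lists, a log2 change of 0.66. Of 30 members 0 passed over all genes and 8 rose when adjusted over the list alone (camera adjusted p = 1.08e-07, adjusted p = 0.252 with an estimated correlation). The median was 0.20 to 0.63 in knockouts 1 to 4 and 1.25 in the 5th. Per1, Cebpd and Irs2 rose without the 5th knockout library, by 0.86, 0.865 and 0.89 on the log2 scale (limma adjusted p = 0.00728, 0.0281 and 0.0479). Per1 is also on the circadian list, Cebpd on the NF-kB list and Irs2 on the FOXO list. Pdk4, an inhibitor of pyruvate dehydrogenase, was 905 ± 287 and 1454 ± 407 (SD, n = 5 each) and did not pass (limma adjusted p = 0.166). FOXO targets had a median of 0.36, with 2 of 38 members rising and 1 falling when adjusted over the list alone (camera adjusted p = 4.00e-04, adjusted p = 0.465 with an estimated correlation). Their median was -0.05 in the 1st knockout, 0.20 to 0.43 in the 2nd to 4th and 1.16 in the 5th. Foxo1, Foxo3 and Foxo4 themselves had log2 changes of 0.20, 0.52 and 0.19, with limma adjusted p-values of 0.443, 0.282 and 0.525. These changes were 0.11, 0.24 and 0.035 without the 5th knockout library. Lists of ubiquitin ligases and muscle atrophy genes (median 0.42 over 19 members, 1 rising over the list alone, camera adjusted p = 7.13e-04) and of autophagy and lysosome genes (0.18 over 33, 0 rising, 0.00756) were called, both with an adjusted p = 0.465 with an estimated correlation. In the 5th knockout library their medians were 1.62 and 0.49, against -0.02 to 0.41 and -0.015 to 0.17 in knockouts 1 to 4. Nedd4 and Ctsd, their most abundant members, had log2 changes of 0.02 and 0.05. The circadian clock list had a median of 0.29, with 3 of 22 members rising over the list alone (camera adjusted p = 4.97e-04, adjusted p = 0.327 with an estimated correlation). Its median was 0.12 to 0.33 in knockouts 1 to 4 and 0.71 in the 5th, and Clock itself had a log2 change of 0.005.

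NF-kB and inflammatory genes had a median log2 change of 0.52, with 5 of 24 members rising and 0 falling when adjusted over the list alone (camera adjusted p = 1.67e-06, adjusted p = 0.252 with an estimated correlation). The median was 0.16 to 0.54 in knockouts 1 to 4 and 0.72 in the 5th. Vcam1, an adhesion molecule, rose without the 5th knockout library (25.8 ± 3.62 in WT, n = 5, and 43.3 ± 9.16 in KO, SD, n = 4, limma adjusted p = 0.018). The level of Nfkb1 was 78.1 ± 2.29 in WT and 78.2 ± 6.45 in KO. Integrated stress response genes had a median of 0.17, with 5 of 31 members rising over the list alone and Psat1 rising over all genes (camera adjusted p = 0.00104, adjusted p = 0.327 with an estimated correlation). The median was 0.12 to 0.18 in knockouts 1 to 4 and 0.60 in the 5th. Slc3a2, an amino acid transporter subunit, rose without the 5th knockout library, by 0.53 on the log2 scale (limma adjusted p = 0.0244). Gdf15 was 0.566 ± 0.331 and 1.57 ± 1.02 (SD, n = 5 each, limma adjusted p = 0.144). Interferon response genes had a median of -0.18, with 2 of 27 members falling over the list alone (camera adjusted p = 0.0356, adjusted p = 0.579 with an estimated correlation), and Parp14 had a log2 change of -0.19. The median was -0.005 to -0.38 in knockouts 1 to 4 and -0.13 in the 5th, and it ranged from -0.20 to 0.18 among WT libraries, so that knockouts 2 to 5 lay within that range. Leaving out the 4th or 5th WT library or the 1st or 3rd knockout library ended this call (camera adjusted p = 0.209, 0.206, 0.269 and 0.0771, medians -0.11, -0.11, -0.14 and -0.12). Unfolded protein response genes were not called (median 0.10 over 28 members, 1 rising over the list alone, camera adjusted p = 0.209), except toward higher signal without the 4th knockout library (median 0.15, camera adjusted p = 0.0366). Hspa5 was 2871 in the 5th knockout library and 436 to 579 in the other knockouts.

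**Figure D3:**
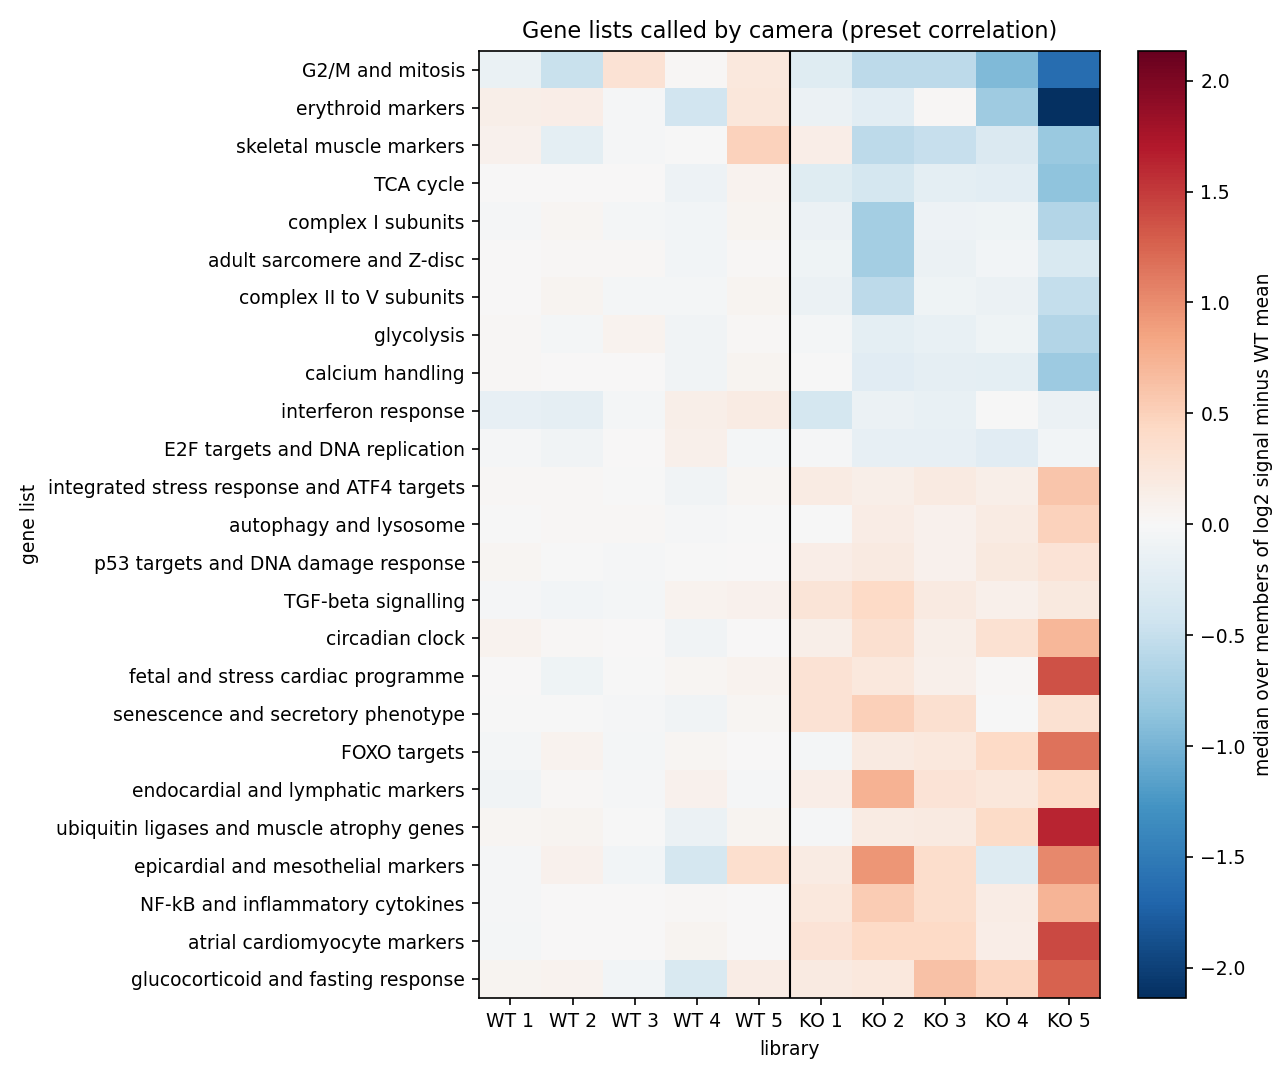
Median over list members of log2 signal minus the WT mean, per library, for the 25 lists called by camera with the preset correlation. Colours run from blue (lower) to red (higher), and the 5th knockout library holds medians of -1.62 for G2/M and mitosis and 1.62 for ubiquitin ligases and muscle atrophy genes.

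Among heart muscle genes, the fetal and stress list was called toward higher signal and the adult sarcomere and calcium handling lists toward lower signal with the preset correlation, and none of the 3 with an estimated one. The fetal and stress list had a median log2 change of 0.31, with 0 of 28 members passing over all genes and, adjusted over the list alone, 4 rising and 1 falling (camera adjusted p = 0.00697, adjusted p = 0.468 with an estimated correlation). Its median was 0.03 in the 4th knockout, within the WT range of -0.10 to 0.08, 0.10 to 0.32 in the 1st to 3rd and 1.36 in the 5th, where Myh7 was 64424 against 81 to 414 in the other knockouts. The adult sarcomere list had a median of -0.30, with 0 of 28 members past either count (camera adjusted p = 0.0303, adjusted p = 0.540 with an estimated correlation). Its median was -0.72 in the 2nd knockout and -0.33 in the 5th, against -0.07 to -0.13 in the others. Leaving out the 2nd knockout ended this call (camera adjusted p = 0.406, median -0.14). Cardiomyocyte markers, a list not called, had medians of -0.72 and -0.74 in the 2nd and 5th knockouts and -0.07 to -0.11 in the others. This list shares Myh6, Ttn and other genes with the sarcomere list, and Ryr2 and Pln with the calcium handling list. Its medians are thus no separate measure of cell content. Of the 18 markers 14 had a negative and 4 a positive log2 change with all libraries. Calcium handling genes had a median of -0.26, with 1 of 27 members rising and 3 falling over the list alone (camera adjusted p = 0.00381, adjusted p = 0.465 with an estimated correlation). The median was -0.006 to -0.24 in knockouts 1 to 4 and -0.77 in the 5th. Ryr2, the sarcoplasmic calcium release channel, and Trdn, its partner triadin, fell without the 5th knockout library, with log2 changes of -0.53 and -0.43 (limma adjusted p = 0.0291 and 0.0411). Myh6 was 44400 ± 1868 and 31917 ± 14066, and Atp2a2 14444 ± 1081 and 9297 ± 2676 (SD, n = 5 each), and neither passed (limma adjusted p = 0.336 and 0.176). Nppb, Acta1, Pln, Ttn and Tpm1 had log2 changes of 0.99, 0.10, -0.05, -0.54 and -0.41 that did not pass. The changes were -0.41 for Myh6, -0.46 for Atp2a2, 0.49 for Nppb and 0.275 for Acta1 without the 5th knockout library. For Myh6 this came from the 2nd knockout, at 16851, against 40515 to 44843 in the 1st, 3rd and 4th and 42646 to 47155 in WT. Atp2a2 was 9926 to 10864 in knockouts 1 to 4 and 12651 to 15529 in WT. Ion channel genes were not called (median -0.05 over 30 members, 1 rising and 1 falling over the list alone, camera adjusted p = 0.581), and Abcc9 had a log2 change of -0.05.

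Nuclear envelope genes other than Lmna were not called as a list (median 0.06 over 26 members, 1 rising over the list alone, camera adjusted p = 0.177). Lmnb1, Lmnb2 and Emd, which encode lamins B1 and B2 and emerin, had log2 changes of -0.29, -0.56 and 0.37 with limma adjusted p-values of 0.274, 0.310 and 0.136. Lmnb2 was 1.88 in the 5th knockout library, and its log2 change was -0.26 without it. Tpr, the most abundant member, had a log2 change of 0.05. Tmem43 rose without the 5th knockout library (33.2 ± 2.89 in WT, n = 5, and 49.2 ± 8.11 in KO, SD, n = 4, limma adjusted p = 0.0219).

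Of the cell type marker lists 5 were called by camera with the preset correlation and 0 with an estimated correlation. Atrial cardiomyocyte markers had a median log2 change of 0.52, with 0 of 15 members passing over all genes and 7 rising over the list alone (camera adjusted p = 0.00136, adjusted p = 0.219 with an estimated correlation). Myl7, the atrial myosin light chain, was 0.291 ± 0.187 in WT and 37.5 ± 32.3 in KO (SD, n = 5 each), with 0.375 in the 4th knockout library. The list median was 0.15 to 0.43 in knockouts 1 to 4 and 1.41 in the 5th. Myl7, Dkk3 and Pam rose without the 5th knockout library (limma adjusted p = 0.0371, 0.0387 and 0.0356), and Pam was 897 ± 24.3 in WT (SD, n = 5) and 1174 ± 138 in that fit (SD, n = 4). Endocardial and lymphatic markers had a median of 0.42, with Plvap as the 1 of 11 members that rose over all genes and 2 rising over the list alone (camera adjusted p = 1.44e-04, adjusted p = 0.261 with an estimated correlation). The median was 0.14 to 0.74 in knockouts 1 to 4 and 0.43 in the 5th. Npr3 rose without the 5th knockout library, by 0.86 on the log2 scale (limma adjusted p = 0.0114). Epicardial and mesothelial markers had a median of 0.50, with 2 of 16 members rising over the list alone (camera adjusted p = 0.00163, adjusted p = 0.465 with an estimated correlation). Their median was 0.95 and 1.03 in the 2nd and 5th knockouts, 0.17 and 0.38 in the 1st and 3rd and -0.28 in the 4th, and it ranged from -0.38 to 0.355 among WT libraries. Clu was 109 ± 16.6 in WT (SD, n = 5) and rose to 166 ± 17.1 with the 5th knockout library left out (SD, n = 4, limma adjusted p = 0.016). Skeletal muscle markers had a median of -0.43, and 1 of 7 members, the calcium channel gene Cacna1s, fell in both counts, from 3.15 ± 0.284 to 1.03 ± 0.413, a call lost in 11 of 23 alternatives (camera adjusted p = 0.0256, adjusted p = 0.327 with an estimated correlation). Their median was 0.14 in the 1st knockout, -0.30 to -0.55 in the 2nd to 4th and -0.79 in the 5th. The call was lost in 8 of 22 alternatives, and the medians ran from -0.52 to -0.04 over all 22. Leaving out the 5th WT library or the 2nd or 3rd knockout library ended it (camera adjusted p = 0.0664, 0.0697 and 0.0585, medians -0.35, -0.28 and -0.34). Ckm had a log2 change of -0.43 that did not pass. Erythroid markers had a median of -0.71 over 7 members with 0 past either count (camera adjusted p = 0.0211, adjusted p = 0.509 with an estimated correlation). This call was lost without the 5th knockout library (camera adjusted p = 0.133), whose median was -2.13, and Fech had a log2 change of -0.12.

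The remaining lists were not called by camera with all libraries. Cardiomyocyte markers had a median log2 change of -0.36 (camera adjusted p = 0.113), endothelial markers one of -0.04 (0.922), fibroblast markers -0.31 (0.922), activated myofibroblast markers -0.31 (0.922), smooth muscle and pericyte markers -0.12 (0.209), macrophage markers -0.02 (0.948), neutrophil and mast cell markers 0.17 (0.581), Schwann cell and neuronal markers 0.12 (0.699) and adipocyte markers 0.08 (0.186). Collagen and matrix genes had a median of -0.37 (0.240), MRTF/SRF and YAP targets 0.10 (0.0778), hypoxia targets -0.01 (0.993), imprinted and fetal growth genes 0.08 (0.130), ribosomal proteins 0.02 (0.901) and cholesterol synthesis genes -0.11 (0.341). Over all genes 0 members of these lists passed, except that Hk2, a hypoxia target, fell and that H19 and Igf2 rose, 2 of 22 imprinted and fetal growth genes. Adjusted over the list alone, 5 imprinted and fetal growth genes rose and 1 fell, 3 hypoxia targets rose and 6 fell, and 2 genes each rose among collagen and matrix, MRTF/SRF and YAP, myofibroblast and endothelial genes. In the other lists of this paragraph at most 1 gene rose, and among all but the hypoxia targets at most 2 fell. For endothelial markers camera pointed up while median and mean (-0.002) lay below 0. For hypoxia targets camera pointed up and fry down, with a mean of 0.115. The means of the Schwann cell list (-0.04) and of ribosomal proteins (-0.002) had the opposite sign to their medians. Without the 5th knockout library the MRTF/SRF and YAP targets were called up (camera adjusted p = 0.0153) and ribosomal proteins down (0.0119), with adjusted p = 0.423 and 0.716 with an estimated correlation. The ribosomal median was -0.81 in the 2nd knockout library, -0.01 to 0.09 in the 1st, 3rd and 4th and 0.705 in the 5th. Leaving out the 2nd instead, ribosomal proteins were called up (median 0.22, camera adjusted p = 1.51e-04), and with both left out, an alternative chosen after the data were seen, they were not called (median 0.06, camera adjusted p = 0.0651). MRTF/SRF and YAP targets were also called up without the 1st WT or the 4th knockout library (camera adjusted p = 0.0467 and 0.0284). Among endothelial genes Vwf rose and Kdr, a VEGF receptor, fell with the 5th knockout library left out, with log2 changes of 0.61 and -0.55 (limma adjusted p = 0.028 and 0.021). Collagen gene levels were low in the 5th knockout library, with a list median of -1.52 there against -0.36 to 0.17 in the others. Fibroblast and activated myofibroblast markers were low there too, with medians of -1.32 and -1.74. These were -0.32 and -0.48 in the 4th, and 0.06 to 0.20 and 0.045 to 0.355 in the 1st to 3rd. Col3a1, Col1a1 and Postn had log2 changes of -1.05, -0.56 and -0.72 with all libraries and of -0.17, -0.03 and -0.16 without the 5th knockout library, and did not pass in either. Neither did Des, Fabp4, Lgmn, Kit, Prnp, Hmgcs1 and Rplp0, with log2 changes between -0.31 and 0.42 with all libraries. Des had log2 changes of 0.39 with all libraries and 0.06 without the 5th knockout, Lgmn of -0.17 and 0.06, Fabp4 of -0.045 and -0.15, Hmgcs1 of -0.20 and -0.08, and Rplp0 of 0.065 and -0.07.

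In the authors' deposited table an FDR under 0.05 was given for 809 entries, 576 higher and 233 lower in the knockout. Of these, 654 were among the genes tested by limma, and the 26 genes called by limma were all among them. Of the 640 genes called without the 5th knockout library, 372 were. An edgeR exact test with common and tagwise dispersions on the recovered reads, chosen after the data were seen, gave 809 calls over all rows and a correlation of 1 with the deposited p-values on the log scale across 14625 genes. In the authors' deposited table the log2 ratio was -1.65 for Lmna, 7.87 for Myh7 and 5.01 for Nppa, with FDR values of 5.35e-13, 4.71e-05 and 2.79e-04.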

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

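The test of transcript length was chosen before its result was seen. The tests of atrial tissue and of a larger size of the same effect were chosen after the 5th knockout library had been seen to stand apart. Among the named genes 38 of 218 groups of 5 libraries held a value whose gap to the nearest other exceeded 0.71 of the range, where chance gives about 1 group in 20. Over all tested genes 5.1% of WT groups and 16.2% of Lmna KO groups did. In 1505 genes the library that stood apart in Lmna KO was the 5th.

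The 5th knockout library held 21 of the 38 values. It lay above the other knockouts with 64424 for Myh7 (81 to 414 in the other knockouts), 12131 for Ankrd1 (671 to 1499), 6767 for Nppa (84.4 to 146), 4791 for Ctgf (79.2 to 170), 4108 for Des (928 to 1585) and 2871 for Hspa5 (436 to 579). It was also above them for Nppb (952), Perp (921), Clu (796), Igfbp3 (396), Per1 (266), Btg2 (249), Pcna (70.8), Cebpd (70.7), Ahsg (69.9), Bmp10 (17.3) and Gdf15 (3.35). It was below them for Atp2a2 (4560 against 9926 to 10864), Ndufs1 (415 against 817 to 876), Cycs (410 against 1044 to 1191) and Lgmn (48.7 against 107 to 114).

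The root mean square deviation of the 5th knockout library from the WT mean was 0.935 on the log2 scale, against 0.311 to 0.54 in the other knockouts. Its deviation from the other 4 knockouts had a rank correlation of 0.007 with transcript length across genes (95.5% of genes had a length). This argues against a steady trend with length as a cause. The length was that of the longest annotated transcript of a gene, not of the form present in the heart. Other effects of length or of RNA quality were thus not excluded. For atrial tissue alone, the deviation of the 5th from WT was 3.01 times that of the 1st knockout library, while the level of Myl7 was 1.49 times as high. A log2 deviation and a level need not rise together, so these ratios do not exclude it. The 4th knockout, with Myl7 at 0.375, deviated by 0.352 and the 1st, with Myl7 at 54.8, by 0.311. The deviation thus did not follow Myl7 between these knockouts. A larger size of the same genotype effect is a candidate explanation for part of the changes. Across genes, which are not independent replicates, the changes in the 5th and in the other 4 knockouts had an r of 0.559 against separate WT libraries, and 0.255 to 0.624 for each of the 4 alone. This r reflects shared direction rather than size. Over the 3 genes called in knockouts 1 to 4 against WT 3 to 5 (Lrat, Lmna and Fam81a), the median ratio of the change in the 5th to theirs was 1.11. This median is the ratio of Lrat (-3.22 against -2.89), which held 2 to 7 reads in every knockout and could hardly fall further. It thus does not show the size of the effect. Fam81a changed more in the 5th, by -3.29 against -1.39. Lmna changed less in the 5th, by -1.08 against -1.85. Medians of collagen, fibroblast and myofibroblast genes, positive in the 1st to 3rd, were -1.52, -1.32 and -1.74 in the 5th (-0.36, -0.32 and -0.48 in the 4th). A larger size alone does not account for these lists. The r does not separate a more advanced state of disease from other differences between animals, which were not tested.

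In the 2nd knockout library Pln (9248), Vcam1 (57.1) and Slc24a2 (14.3) lay above the other knockouts and Atp5b (4623) below them. In the 4th knockout library Parp14 (49.2) and Ankrd35 (0.857) lay above the others. In the 4th WT library Perp (202) and Dkk3 (12.3) lay above the other WT libraries, and Ttn (67191), Hk2 (285) and Efcab2 (41.8) below them. In the 5th WT library Des (1387), Nr4a1 (26.1), Rasgef1b (18.9), Nmrk2 (6.85) and Gdf15 (1.15) lay above the others, and in the 1st Hspa5 (659) did.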

How the results depend on the processing

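The alternatives with edgeR's exact test, with the 2nd and 5th knockout libraries left out and with an estimated correlation without the 5th knockout library were chosen after the data were seen. The fall of Lmna kept its direction and its call in all 24 alternatives, with log2 changes from -1.83 to -1.55, both ends from leaving out a library. The count of 26 changed genes moved by over 1.5 times with a minimum mean signal of 5 (14 genes), a log2 change of at least 1 (15), an adjusted p under 0.01 (6), library weights (2280), DESeq2 (786), the exact test (808), the exact test without the 5th knockout library (1051) and the 2nd and 5th knockout libraries left out (1370). Leaving out 1 library gave 6 to 640 genes: 6, 7, 6, 9 and 9 without WT libraries 1 to 5, and 19, 14, 11, 39 and 640 without knockouts 1 to 5. Library weights gave the 5th and 2nd knockout libraries 0.072 and 0.159, the lowest of all. Apart from the smaller samples and stricter limits, the cause was not tested. The remaining alternatives that kept all 10 libraries, other than the block, gave 20 to 32 genes. Of the called gene lists, 0 of 25 held with an estimated correlation, with or without the 5th knockout library, and 11 with fry. Leaving out 1 library kept 23 to 25 of them, among 23 to 27 called lists.

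With the replicate number as a block (replicate block) 35 genes, 29 of them higher, and 24 lists were called, 15 of the genes and 24 of the lists shared with the fit without it, and Lmna had a limma adjusted p of 0.0268. Same-numbered libraries had correlations of 0.182, -0.134, 0.171, 0.12 and 0.03 between their deviations, and only those numbered 3 correlated best with each other, so the numbers were not read as pairs.

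Over all alternatives, values of single genes kept direction and call 2162 times, gained a call 220 times, lost it 143 times and changed direction 51 times. For lists these counts were 861, 12, 85 and 31. No gene or list that changed direction was called with all libraries, and the cause was not tested. Log2 changes with the opposite sign were, with the 2nd and 5th knockout libraries left out, -0.056 for Nedd4, 0.035 for Abcc9, -0.003 for Tpr, -0.171 for Hspa5, 0.069 for Nfkb1, -0.113 for Clock, 0.13 for Fabp4, 0.047 for Lgmn, -0.016 for Foxo1 and 0.038 for Col1a1. With library weights they were -0.047 for Nedd4, -0.023 for Ctsd, -0.001 for Pcna, 0.001 for Abcc9, -0.138 for Hspa5, 0.077 for Nfkb1, -0.08 for Clock, 0.168 for Fabp4, 0.01 for Lgmn and 0.124 for Col1a1. With edgeR's quasi-likelihood test, DESeq2 and the exact test they were 0.012, 0.012 and 0.003 for Nfkb1, 0.034, 0.033 and 0.025 for Fabp4, and -0.017, -0.018 and -0.026 for Acta1. Median-of-ratios scaling gave 0.008 for Nfkb1 and upper-quartile scaling -0.01 for Clock. Leaving out 1 library gave -0.034 to 0.048 for Nedd4, -0.111 to 0.075 for Abcc9, -0.153 to 0.216 for Tpr, -0.203 to 0.477 for Hspa5, -0.034 to 0.044 for Nfkb1, -0.105 to 0.079 for Clock, -0.074 to 0.168 for Rplp0, -0.148 to 0.189 for Fabp4, -0.244 to 0.062 for Lgmn, -0.289 to 0.409 for Acta1 and -0.151 to 0.001 for Pln.

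For lists the direction is that of camera or fry and the value printed is the median log2 change, which can keep its sign. With an estimated correlation and the 5th knockout library left out, the direction changed for collagen and matrix (-0.028), unfolded protein response (-0.098), ribosomal proteins (-0.172), fibroblast (0.012), myofibroblast (-0.009) and macrophage genes (0.119). With the 2nd and 5th knockout libraries left out it changed for unfolded protein response (-0.115), fibroblast (-0.043), myofibroblast (-0.066), macrophage (0.01) and Schwann cell genes (-0.003). For hypoxia targets it changed with a pseudocount of 1 (-0.01), no filter (-0.01), median-of-ratios scaling (-0.001) and fry (-0.01), and for macrophage markers with a minimum mean of 5 (-0.018). Leaving out 1 library gave medians of -0.496 to -0.028 for collagen and matrix, -0.098 to 0.163 for unfolded protein response, -0.037 to 0.086 for hypoxia targets, -0.172 to 0.219 for ribosomal proteins, -0.43 to 0.012 for fibroblast, -0.506 to -0.009 for myofibroblast, -0.114 to 0.076 for endothelial, -0.21 to 0.119 for macrophage and 0.051 to 0.235 for Schwann cell genes. Depth limited the low genes: 1 read was worth 0.0447 to 0.0672 signal units, and genes with a mean under 1 were not tested.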

Other observations

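The list of ERK feedback genes, the genes Dusp5, Spry1, Lrat, Rbm46, Ankrd35, Myl4, Sln, Sbk2 and Bmp10, and the tests of atrial tissue and of flanking DNA were chosen after the results were seen. Myl7 came from the naming rule as applied, after the 5th knockout library had been seen to stand apart, to the fit without it. Etv5, Lmna, Nppa and the counts of splits followed rules fixed before. Genes under feedback control by ERK signalling were called toward higher signal as a list with the preset correlation, with a median log2 change of 0.34 over 18 measured members (camera adjusted p = 1.37e-05, adjusted p = 0.149 with an estimated correlation). Etv5 was the 1 member that rose over all genes, and 7 rose and 0 fell when adjusted over the list alone. Without the 5th knockout library the median was 0.35 (camera adjusted p = 1.75e-06) and 4 members rose, among them Dusp5, a phosphatase of ERK, and Spry1, a feedback inhibitor of the pathway (limma adjusted p = 0.0225 and 0.0252). Dusp5 was 5.88 ± 1.04 in WT and 11.6 ± 2.59 in KO, and Spry1 was 39.6 ± 4.02 and 54.7 ± 4.88 (SD, n = 5 each, limma adjusted p = 0.0687 and 0.0747 with all libraries). Other feedback inhibitors on the list passed in neither fit. With all libraries log2 changes were 0.79 for Dusp4, 0.4 for Dusp6, 0.23 for Spred1 and 0.28 for Spred3. They were 0.12 for Spry2, -0.12 for Spry4, 0.03 for Spred2 and 0.09 for Il17rd. Ccnd1, also on the list, had one of -0.505 and did not pass. The list was written because Etv5 had been seen to rise, so its direction is not independent of that gene.

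Lrat, which makes retinyl esters for vitamin A storage, fell to 0.217 ± 0.12 from 5.22 ± 0.99 in WT (SD, n = 5 each, limma adjusted p = 1.96e-05). It lay below every WT library in 5 of 5 knockouts. On chromosome 3 (mm10), Lrat at 82892582 to 82903974 lies 5.59 Mb from Lmna. Its neighbour Rbm46 (82836523 to 82876483) rose from 0.57 ± 0.436 to 2.73 ± 0.625, and Ankrd35 (96670131 to 96691034), 8.19 Mb from Lmna on the other side, fell from 1.66 ± 0.346 to 0.535 ± 0.183 (limma adjusted p = 0.0259 and 0.0372). Of 23 alternatives Lrat kept its call in all, Rbm46 lost it in 8 and Ankrd35 in 9. Leaving out the 1st or 3rd WT library ended both calls (limma adjusted p = 0.0938 and 0.101 for Rbm46, 0.0938 and 0.143 for Ankrd35).

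DNA of another strain carried along with the targeted gene may account for changes near Lmna. Of 209 genes within 10 Mb 3 were called, against 22 of 12644 elsewhere (Fisher's exact p = 0.00749, two-sided), but Lrat and Rbm46, 2 of the 3, had prompted this test, so its p-value restates that observation and is no independent evidence. Within 5 Mb 0 of 105 genes were called (95% interval of the odds ratio 0 to 19.6), and with the 2 prompting genes left out 1 of 207 within 10 Mb (exact p = 0.312), and neither value decides. Without the 5th knockout library 14 of the 209 and 3 of the 105 were called (odds ratios 1.38, 95% interval 0.737 to 2.39, and 0.56, 0.113 to 1.69). This explanation and an effect of the genotype cannot be told apart, since any such DNA would come with the targeted gene. The strain of the flanking DNA is not given in the sources used here, and whether the knockouts carry DNA of another strain was not tested.

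Myl7 lay above every WT library in 4 of 5 knockouts, and tissue of the atria carried over at dissection may account for the higher atrial genes. Myl7 was 54.8, 36.9, 13.9, 0.375 and 81.5 in knockouts 1 to 5, and Myl4, another atrial light chain, was 50.2, 45, 15.5, 2.36 and 107. Over the genes near absent in WT the ratio of rises to Myl7 in knockouts 1, 2, 3 and 5 had a median span of 14.6-fold. It was 3.48 for Sln, 14.6 for Sbk2 and without bound for Bmp10, at 0 in 2 of these. Dhrs9, at 0.121 in WT and 0.609 in the 5th knockout, was not in this set, and its span was without bound. The median thus depends on which genes are taken. Carried-over atria and expression in the ventricle cannot be told apart for them with so few genes near the floor. Among the other atrial markers the span was 1.47 for Myl4, 2.2 for Dkk3 and 2.31 for Pam. It was 5.38 or more, or without bound, for the rest. A span without bound came from genes that did not exceed their WT mean in at least 1 of these knockouts. Not every atrial marker rose, therefore. For Myl4, Dkk3 and Pam carried-over atria stay open. For Nppa the ratio was 82.7 in the 5th knockout and 1.65 to 2.89 in knockouts 1 to 3, a span of 50.3-fold, which argues against atrial tissue with the same share of Nppa as its whole source in the 5th, while for knockouts 1 to 3 (span 1.75-fold) it stays open. In the 4th, where Nppa was 146 (24.9 to 71.2 in WT) and Myl7 lay within its WT range, the ratio was still 47.3 times the highest of knockouts 1 to 3 with 2 WT SD taken off the rise of Nppa and added to that of Myl7, which argues against such tissue there too.

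Of 100 splits of the 10 libraries into 5 and 5, only 1, the real one, gave as many as 26 called genes, and the highest of the others gave 1. Chance is thus an unlikely source of the count of genes, as far as 100 of 126 possible splits can show. For gene lists 11 of 100 splits, the real one with 25 included, gave as many, and the highest other gave 29, so chance was not excluded for the count of lists.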
